A study of Mus musculus with 18 samples.

How the data were processed

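Total RNA of mouse embryonic stem cells (strain C57BL/6) that were differentiating as embryoid bodies was labelled with biotin and hybridised to Affymetrix gene expression arrays, 1 sample per array. Embryoid bodies are free-floating aggregates in which stem cells leave pluripotency and form early derivatives of the germ layers. Per the labels' treatment protocol, cultures received 0.25 mM thalidomide or the vehicle (0.25% DMSO) from day 3 of the embryoid body stage, for 24, 48 or 72 h. The series description calls the controls unexposed, and the controls' source names count hours from embryoid body formation. The controls were read here as vehicle controls of the same hours, which the labels do not settle. The 18 arrays formed 6 groups (control and exposed at 3 times) of 3 arrays, which the labels call biological replicates. Titles of 12 arrays (the 9 controls and the 3 exposed arrays of 24 h) carry a re-analysis tag, and those of the 6 exposed arrays of 48 h and 72 h do not. The labels do not say what was analysed again.

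The deposited values are log2 signals, 1 per probe set and array, made by robust multi-array average (RMA) in Affymetrix Expression Console 1.3, per the submitters' processing notes. The genome build is not given in the sources used here, so no coordinates are printed. The sorted values of any 2 arrays differed by at most 0.19 log2 units, as quantile-normalized values do, and array medians ran from 5.367 to 5.462. No further normalization was applied. Quantile normalization gives all arrays nearly the same distribution, so changes are relative to the other probe sets of an array, and a shift of most transcripts in 1 direction would not be seen. No background or detection values were used, so dim probe sets could not be set against background. The number of arrays limits the precision of each value.

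Of 41345 probe sets, 25335 were listed in the table of genes built from the platform annotation, and 16010 were not named here. A single gene symbol was given for 23521 probe sets and several symbols for 1814, which were named after none of them. Gene identifiers of 23328 probe sets matched the RefSeq gene table of mouse assembly GRCm38.p6, and no symbol changed. A gene with several probe sets (1082 genes) was represented by the probe set with the highest mean over all arrays, which left 22180 genes.

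Each gene was fitted with limma 3.58.1 in R 4.3.3 (lmFit with 1 mean per group over all 18 arrays, contrasts.fit, eBayes without trend or robust options). The fit had 12 residual degrees of freedom and 4.35 prior degrees of freedom. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over the 22180 genes within each contrast, and the threshold was an adjusted p under 0.05. Adjusted p-values of single genes are limma's throughout, log2 changes are given ± their standard error (SE), and group levels as mean ± SD. The contrasts were exposed minus control at each time, their mean over the 3 times, the pairwise differences of the exposure effect between times, and control times against each other. A two-sided rank test on 3 against 3 arrays cannot go below an exact p of 0.1, so no such test was used.

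Gene lists were written before the data were examined and tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a contrast. An estimated correlation per list was the alternative. The lists covered naive and core pluripotency, post-implantation epiblast, primitive streak and nascent mesoderm, definitive endoderm, extraembryonic endoderm, cardiac genes, blood and endothelium, neural ectoderm, limb development, Hox genes, angiogenesis signalling, the cereblon ligase with its known thalidomide-class substrates, the NRF2 antioxidant response, p53 targets, the unfolded protein and integrated stress response, cholesterol synthesis, the mitotic cell cycle, glycolysis and hypoxia, canonical Wnt, BMP and FGF-ERK targets, the retinoic acid response, aryl hydrocarbon receptor targets, trophoblast, mesenchyme and matrix, germ cells and the two-cell-like state. Ribosomal protein genes, mitochondrially encoded transcripts, small nucleolar RNAs and replication histones served as signs of RNA quality and loading. Of 31 lists, 30 had at least 5 measured members. The mitochondrially encoded list had 0 measured members and no result.

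Named genes followed a rule set before the data were examined. Per exposure contrast it took the 8 genes up and the 8 down with the largest change among those past the threshold whose exposed arrays all lay on one side of all controls, without predicted loci. It added up to 3 called members of each list, or the member with the smallest p where none was called, and Crbn and Sall4 always. For each difference of effects between times it took the 6 genes with the smallest adjusted p, and for control time the same rule as for exposure. Further genes are said in the text to have been chosen after their values were seen. Histones, ribosomal protein genes, defensins (Defa), kallikreins (Klk1b) and Tcstv genes have near-identical copies to which probes may also bind, so their values are uncertain as to the copy.

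The fit was tested on simulated data with the real means and spreads, in which 67, 67 and 66 genes were changed 1.5-fold, 2-fold and 3-fold. For the 24 h contrast, 68.7%, 97% and 98.5% of these genes were recovered, with 6 false calls among 22180 genes. The shares were 76.1%, 98.5% and 100% for 48 h with 11 false calls, and 77.6%, 95.5% and 100% for 72 h with 7. In a simulation of the 72 h contrast with 20 lists, the list of 25 genes shifted by -0.3 was called and 0 of the others were. The simulated genes varied independently of each other, whereas the estimated correlation was 0.45 in the real cardiac list and 0.26 in the neural one. The simulation therefore does not test whether the preset correlation suits the real lists.

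The design, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The alternatives were an eBayes fit with an intensity trend and robust option, a fit with only the groups of a contrast, all probe sets tested, a filter at the median signal (5.77, leaving 11090 genes), cyclic loess between arrays, the mean of a gene's probe sets, array weights, the replicate number as a block, an added limit of 1.5-fold, and leaving out each replicate in turn. Leaving out the third replicate of both 72 h groups was added after the data were seen. The mean of a gene's probe sets leaves the values of a gene with a single probe set as they are. Passing in that setting therefore adds little for such genes. The overlap of calls was tested with a one-sided Fisher exact test across genes, which are not independent replicates. The test does not allow for the spread of a gene that the contrasts share. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.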

Results

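The series asked which early changes of gene expression thalidomide causes in differentiating mouse embryonic stem cells. Thalidomide binds cereblon, the substrate receptor of a ubiquitin ligase, and is a human teratogen. Gene expression was measured on 18 arrays from embryoid bodies treated from day 3 with 0.25 mM thalidomide or 0.25% DMSO vehicle and collected at 24, 48 and 72 h, with 3 biological replicates in each of the 6 groups. The treatment protocol names the vehicle, whereas the series description calls the controls unexposed, and the source names of the controls count hours from embryoid body formation. A vehicle effect or a difference in stage within the exposed-minus-control values is therefore not ruled out by the labels. Signals are on the deposited log2 scale over 22180 genes. Within a group, arrays correlated across genes at r = 0.992 to 0.996, and the smallest SD of the difference between 2 replicates was 0.183, so no 2 arrays of the same group were copies of each other. The lowest correlation between arrays of different groups was 0.973.

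Time in culture separated the arrays most. The first principal component held 44.4% of the variance and ordered the 24, 48 and 72 h samples, with scores from -27.7 to -24.9, 2.3 to 9.6 and 27.4 to 30.9 in control and -28.3 to -26.3, -4.5 to 2.4 and 14.6 to 23.2 in exposed arrays. The second held 10.8% and separated exposed from control arrays at 24 h and 48 h, whereas at 72 h its scores for the 2 treatments overlapped. The exposed arrays of 48 h and 72 h lack the re-analysis tag that their controls carry, so at these 2 times the tag and the treatment cannot be told apart. All 6 arrays of 24 h carry it.

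**Figure D1:**
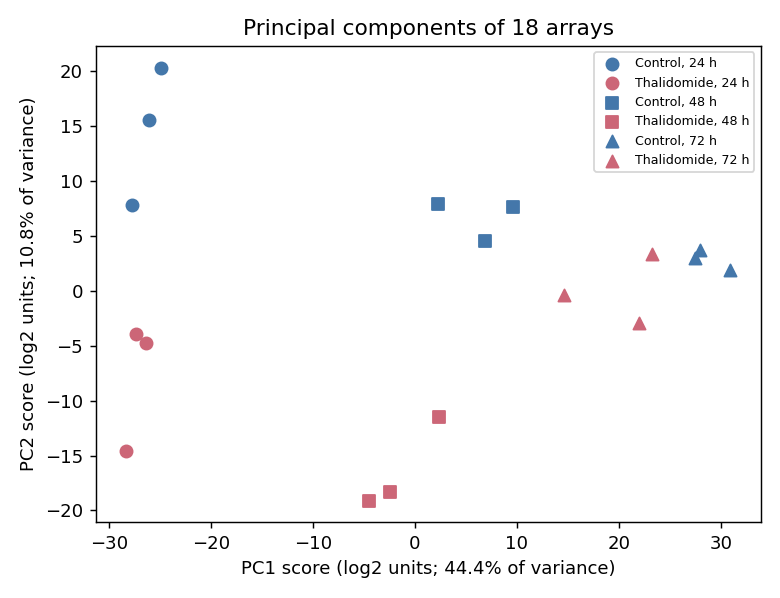
Scores of the 18 arrays on the first and second principal components of the centred log2 signals (44.4% and 10.8% of the variance), with colour for treatment and symbol shape for time. Control and exposed arrays part along the second component at 24 h and 48 h, and at 72 h they overlap on it but part along the first.

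The control arrays show the course of differentiation against which exposure is read. Between 24 h and 72 h most genes of the primitive streak, the structure through which mesoderm and endoderm form, fell, as did 13 of 24 genes of the pluripotency list, where 2 rose. Nanog, a core pluripotency factor, fell by 4.31 on the log2 scale from 9.13 ± 0.21 to 4.82 ± 0.33 (SD, n = 3; adjusted p = 2.64e-09). Mixl1 and Eomes, transcription factors of the streak, had log2 changes of -4.53 and -3.76. Transcripts of heart muscle, smooth muscle and matrix rose: the cardiac actin gene Actc1 rose by 4.43 on the log2 scale to 9.44 ± 0.03 (SD, n = 3; adjusted p = 4.72e-08), the troponin gene Tnnt2 by 4.09 and the smooth muscle actin gene Acta2 by 4.57. The largest rise under the naming rule was that of Igfbp5, a secreted binder of insulin-like growth factors, at 32.4-fold (log2 change 5.02).

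Of 22180 genes, 6095 changed between 24 h and 72 h in control (2914 up and 3181 down), 1664 of them at least 1.5-fold. The balance was 3246 up and 2836 down after cyclic loess and 3986 up and 3714 down with all probe sets tested. From 24 h to 48 h 3023 genes changed (1536 up, 1487 down, or 1797 up and 1805 down with array weights). From 48 h to 72 h 1448 genes changed (804 up, 644 down). Of 30 lists 19 passed camera between 24 h and 72 h. The primitive streak list had a median log2 change of -1.57, with 22 of 26 members down and 1 up both over all genes and adjusted over the list alone (adjusted p = 3.4e-18). It was the only list called with an estimated correlation as well (adjusted p = 0.028 with an estimated correlation). For the cardiac list, 21 of 25 members rose (22 adjusted over the list alone) and the median was 1.87 (adjusted p = 4.43e-21, and adjusted p = 0.055 with an estimated correlation). The endothelial cadherin gene Cdh5 rose by 3.11 on the log2 scale, the BMP-responsive gene Id2 by 2.52 and the retinoic acid receptor gene Rarb by 2.22, each with its list.

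The other called lists had smaller medians, and none was called with an estimated correlation (lowest adjusted p = 0.055 with an estimated correlation). Medians above 0 were seen for mesenchyme and matrix (0.79), BMP targets (0.68), angiogenesis signalling (0.54), blood and endothelium (0.41), the retinoic acid response (0.38), Hox genes (0.32), limb development (0.20) and the cereblon ligase list (0.16). Medians below 0 were seen for the epiblast (-0.47), p53 targets (-0.42), canonical Wnt targets (-0.40), FGF-ERK targets (-0.33), pluripotency (-0.31), cholesterol synthesis (-0.24), the NRF2 response (-0.23), ribosomal protein genes (-0.19) and the mitotic cell cycle (-0.10). The limb call was lost among genes at or above the median signal (adjusted p = 0.0764) and the mitotic call after cyclic loess (adjusted p = 0.0721), and each in 2 of the fits that left out 1 array. With its brightest probe set Sall4, a zinc finger factor of stem cells and limb buds, fell by 0.57 on the log2 scale over the control course (adjusted p = 7.55e-06). As the mean of its probe sets it fell by 0.19, which did not pass (adjusted p = 0.0866). Crbn, which encodes cereblon, had a change of -0.16 (adjusted p = 0.224).

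After 24 h of thalidomide, most genes that changed fell. The largest decrease under the naming rule was that of Sdhc, which encodes a membrane subunit of mitochondrial succinate dehydrogenase. Its signal went from 8.77 ± 0.03 in control to 7.50 ± 0.08 in exposed cells (SD, n = 3), a change of -1.27 ± 0.08 (SE; adjusted p = 8.21e-07). Bod1, which acts in chromosome alignment at mitosis, had a change of -1.01 ± 0.09 (SE), and Mrpl34, a protein of the mitochondrial ribosome, -0.86 ± 0.11 (SE). As the mean of its probe sets the change of Bod1 was -0.75. Bst2, an interferon-inducible antiviral membrane protein, had a change of -0.91 (adjusted p = 0.00216), and the histone gene H2bc12 one of -1.07 (adjusted p = 7.47e-05).

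Dexi, a gene of unknown function next to an autoimmune disease locus, rose at 24 h from 7.53 ± 0.08 to 8.55 ± 0.13 (SD, n = 3; adjusted p = 2.56e-05). The tight junction gene Cldn4 rose by 0.70 on the log2 scale. Klra14-ps (1.06), Defa41 (0.78), Ugt2b37 (0.77) and Ly6g (0.71) also passed, at control signals of 3.20, 3.61, 2.78 and 3.47, which are in the dimmest of 4 equal bins of genes. Of 13 alternative settings Klra14-ps and Defa41 passed in 12 and Ugt2b37 in 8. Slc2a3, a glucose transporter, rose by 0.61 on the log2 scale (adjusted p = 0.000136). Sdhc, Bod1, Mrpl34, Bst2, H2bc12, Dexi, Cldn4 and Slc2a3 passed in all 14 alternative settings.

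Over all genes, 1521 changed at 24 h, 316 up and 1205 down (79.2% down), and 122 of them by at least 1.5-fold. The fall was partly tied to brightness: the median change was 0.054 in the dimmest of 4 equal bins of genes and -0.075 in the brightest. After cyclic loess between arrays, 1044 genes were called, 446 up and 598 down (57.3% down), 816 of them among the 1521.

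**Figure D2:**
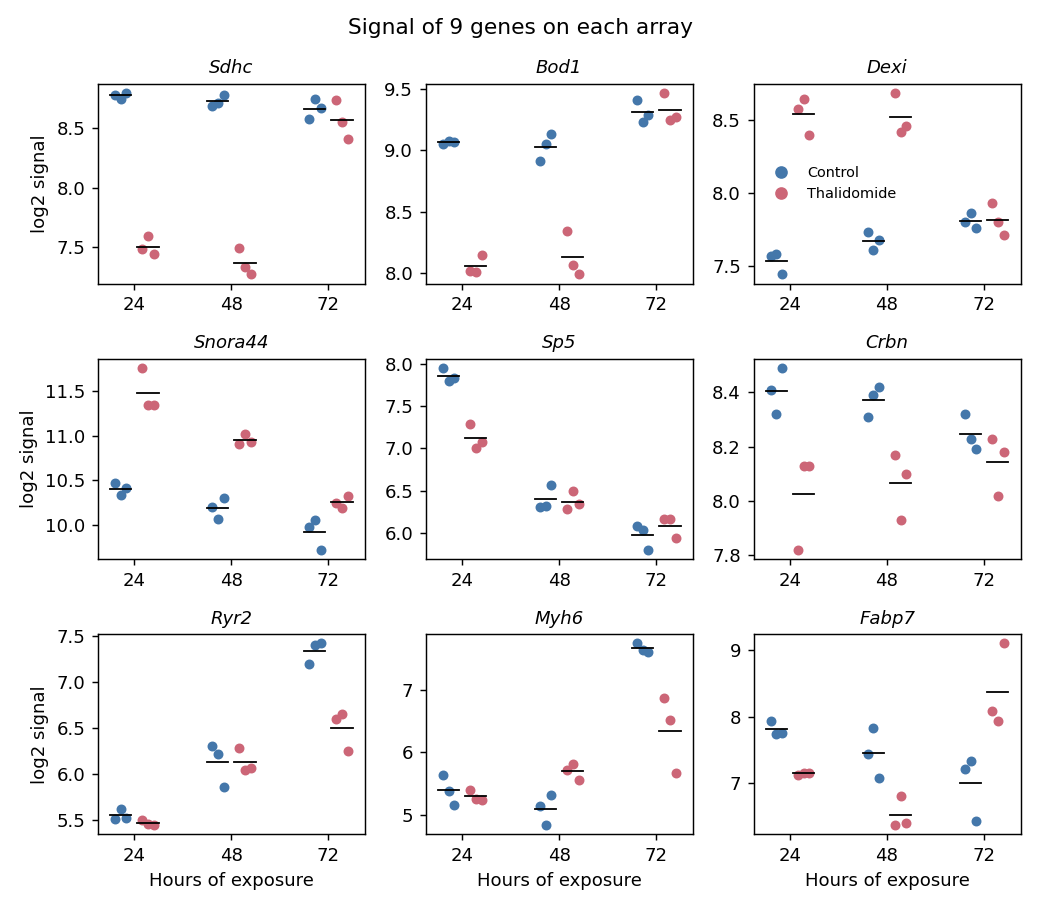
Log2 signal of 9 genes on each array by hours of exposure. Points are arrays (3 per group), bars are group means and colours mark treatment. Sdhc and Bod1 lie lower and Dexi higher in exposed cells at 24 h and 48 h but not at 72 h.

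Genes of the primitive streak were lower at 24 h. The Wnt target Sp5 had a change of -0.73 ± 0.10 (SE; adjusted p = 0.000944), Wnt8a one of -0.60 (adjusted p = 0.0188) and Fgf8, a signal that patterns the streak, one of -0.49 (adjusted p = 0.0456), while Cdx4, a regulator of posterior identity, rose by 0.47 on the log2 scale (adjusted p = 0.00759). The list of 26 had a median of -0.26, with 3 members down and 1 up over all genes, and 9 down and 1 up adjusted over the list alone (adjusted p = 0.00777, but adjusted p = 0.73 with an estimated correlation). Its call was lost without the third exposed replicate of 24 h (median -0.18) and among genes at or above the median signal (adjusted p = 0.203). Tdgf1, the Nodal co-receptor of pluripotent cells and early mesoderm, had a change of -0.75 (adjusted p = 0.0432). Of 14 alternative settings Wnt8a passed in 9, Fgf8 in 7 (-0.66 to -0.35) and Tdgf1 in 4, and Cdx4 passed in 12 of 13.

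Mitotic genes and transcripts used to watch RNA quality moved as well. Cdk1, the kinase that drives entry into mitosis, and the kinase gene Aurkb had changes of -0.35 and -0.32 that passed in 7 and 4 of 14 alternative settings, and the mitotic list a median of -0.07 over 19 members (2 down, 3 adjusted over the list alone; adjusted p = 0.0234, and adjusted p = 0.73 with an estimated correlation). After cyclic loess the median of this list was -0.01 and the call was lost, as it was without the third control (adjusted p = 0.177) or the first exposed replicate of 24 h (adjusted p = 0.0883). Small nucleolar RNAs, which guide modification of ribosomal RNA, rose in 17 of 73 members and in 30, with 1 down, adjusted over the list alone, with a median of 0.24 (adjusted p = 1.33e-13, and adjusted p = 0.73 with an estimated correlation). Snora44 rose by 1.07 on the log2 scale and Snord104 by 0.91. Without the first exposed replicate of 24 h the median of this list was 0.15. Ribosomal protein genes had a median of -0.13, with 7 of 63 members down and 2 up (15 and 2 adjusted over the list alone; adjusted p = 0.000217, and adjusted p = 0.73 with an estimated correlation), among them Rpl32 at -0.48 and Rps3 at -0.32. After cyclic loess that median was -0.07. Replication histones had a median of -0.13, with 4 of 25 members down (7 adjusted over the list alone; adjusted p = 0.0234, and adjusted p = 0.73 with an estimated correlation). This call was lost without the third control (adjusted p = 0.102) or the second exposed replicate of 24 h (adjusted p = 0.269). Among genes at or above the median signal the mitotic (adjusted p = 0.38), ribosomal (adjusted p = 0.0873) and histone (adjusted p = 0.412) calls were lost as well.

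No other list passed at 24 h, though single members did. In the list of the cereblon ligase (adjusted p = 0.858), Crbn had a change of -0.38 ± 0.09 (SE), from 8.41 ± 0.09 to 8.03 ± 0.18 (SD, n = 3; adjusted p = 0.0215), and Cul4a, the scaffold of the same ligase, one of -0.34 (adjusted p = 0.00888). Crbn passed in 9 of 14 alternative settings and Cul4a in 12. Without the first exposed replicate of 24 h the change of Crbn was -0.27 and did not pass. Of the antioxidant genes controlled by NRF2 (adjusted p = 0.0562), 4 of 18 fell, including Gclm (-0.34), which encodes a subunit of the enzyme for glutathione synthesis, and catalase (Cat, -0.26). They passed in 12 and 7 of 14 alternative settings. Of the laminin genes of basement membranes, Lamc1 and Lama1 had changes of 0.50 and Lamb1 one of 0.32 (extraembryonic endoderm list, adjusted p = 0.107), which passed in 11, 5 and 9 of 14 alternative settings. This list was called after cyclic loess (0.13, adjusted p = 0.0132) and among genes at or above the median signal (0.10, adjusted p = 0.00517). Cholesterol synthesis was called after cyclic loess (0.09, adjusted p = 0.0136), the NRF2 list without the second control (adjusted p = 0.0286) and FGF-ERK targets without the first exposed replicate of 24 h (adjusted p = 0.0244). Among p53 targets (adjusted p = 0.725) the cell cycle inhibitor gene Cdkn1a had a change of -0.34 and Perp the same, which passed in 4 and 5 of 14 alternative settings. Cyp26a1, which breaks down retinoic acid, had one of -0.58, Tgfb1 one of -0.62 and the BMP target Id3 one of -0.37, which passed in 10, 10 and 9. The cardiac, blood, neural and Hox lists had 0 called members in limma, where 4710 of all genes had an unadjusted p under 0.05 and 1109 would by chance.

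After 48 h several of the largest decreases of 24 h were again among the largest. Sdhc went from 8.73 ± 0.05 to 7.36 ± 0.11 (SD, n = 3), a change of -1.36 ± 0.08 (SE; adjusted p = 2.88e-07). H2bc12 (-1.17), Bst2 (-0.95), the zinc finger gene Zfp97 (-0.92) and Bod1 (-0.90) were again among the largest decreases, and Dexi rose by 0.85 on the log2 scale (adjusted p = 0.000151). The change of Bod1 was -0.55 as the mean of its probe sets, which still passed. Myl7, the atrial myosin light chain, had a change of -1.09 (adjusted p = 0.0482), which passed in 5 of 14 alternative settings. Syne1, a nuclear envelope protein, rose by 0.67 on the log2 scale with its brightest probe set, and by 0.01 (adjusted p = 0.929) as the mean of its probe sets, within a range from 0.01 to 0.73.

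At 48 h 1349 genes changed, 410 up and 939 down (69.6% down), 123 of them at least 1.5-fold. Cyclic loess gave 1021 calls, 415 up and 606 down (59.4% down), 815 of them among the 1349, and the filter at the median signal gave 1950, of which 80.5% were down. The median change was 0.056 in the dimmest bin and -0.058 in the brightest.

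Markers of definitive endoderm, the germ layer of gut and lung, were lower at 48 h. Cxcr4, a chemokine receptor on these cells, had a change of -0.42 ± 0.07 (SE; adjusted p = 0.00451) and the junction gene Cldn6 one of -0.41 (adjusted p = 0.0271), which passed in 13 and 8 of 14 alternative settings. The list had a median of -0.26 over 11 members, with 2 down and 3 adjusted over the list alone (adjusted p = 0.00531, and adjusted p = 0.34 with an estimated correlation). After cyclic loess its median was -0.23 and the call was lost (adjusted p = 0.0732), as it was among genes at or above the median signal (adjusted p = 0.126). Small nucleolar RNAs had a median of 0.11, with 5 of 73 up and 10 adjusted over the list alone (adjusted p = 0.000484, and adjusted p = 0.90 with an estimated correlation). Replication histones had a median of -0.25, with 2 of 25 down and 1 up (12 and 1 adjusted over the list alone; adjusted p = 6.22e-06, and adjusted p = 0.34 with an estimated correlation). Another assignment of the 48 h arrays to exposed and control called 5 lists, against 3 with the real one. The number of lists called at 48 h therefore does not set exposure apart from wrong labels.

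Single members of other lists passed at 48 h. Otx2, a transcription factor of epiblast and anterior brain, had a change of -0.50 (adjusted p = 0.0258; 9 of 14 alternative settings). The p53 targets Cdkn1a (-0.51) and Tnfrsf10b (-0.40), a death receptor gene, fell, and passed in 13 and 9. Tgfb1 (-0.70) and the ERK-responsive gene Ier3 (-0.58) fell further than at 24 h in value, although no gene's effect differed between 24 h and 48 h by test. Hoxb4 rose by 0.49, the collagen gene Col1a1 by 0.44 and Slc2a3 by 0.37 on the log2 scale, which passed in 6 of 13, 12 of 14 and 13 of 14 alternative settings. Mesenchyme and matrix genes were called at 48 h among genes at or above the median signal (0.12, adjusted p = 0.028), and Hox genes in 3 and FGF-ERK targets in 1 of 10 alternative settings. Cul4a had a change of -0.33 (adjusted p = 0.0124; 10 of 14 alternative settings) and Crbn one of -0.31 (adjusted p = 0.0562).

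The 24 h and 48 h changes overlapped, and their group means come from different arrays on both sides. The spread of each gene, however, was estimated from the arrays of all groups together. Genes with a small spread are therefore more easily called at both times, so the calls are not independent. In all, 501 genes fell at both times where 51 would by independent lists, and 66 rose at both where 5.84 would (one-sided Fisher exact test for the latter, p = 4.27e-50). The expected numbers and the p-value do not allow for the shared spread. A shared spread does not set the direction of a change, and only 2 genes were called in opposite directions. Of the 122 and 123 genes changed at least 1.5-fold, 34 were shared. The 501 genes had median changes of -0.40 at 24 h and -0.38 at 48 h, but -0.04 at 72 h, and the 66 had 0.35, 0.34 and 0.01. Across all genes, which are not independent replicates, the effects correlated at r = 0.49 between 24 h and 48 h, 0.09 between 24 h and 72 h and 0.14 between 48 h and 72 h.

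At 72 h heart muscle genes were lower in exposed embryoid bodies, and all 25 members of the cardiac list had changes below 0. Ryr2, the calcium release channel of heart muscle, went from 7.34 ± 0.12 to 6.50 ± 0.22 (SD, n = 3), a change of -0.84 ± 0.12 (SE; adjusted p = 0.0328). Cacna1c, the main calcium channel of the heart cell membrane, went from 7.21 ± 0.08 to 6.42 ± 0.24 (SD, n = 3), a change of -0.79 ± 0.11 (SE; adjusted p = 0.0328). These were the 2 genes called at 72 h, both down, and each passed in 7 of 15 alternative settings. The myosin heavy chain gene Myh6 had a change of -1.32 (adjusted p = 0.0721). Actc1 (-1.45, adjusted p = 0.13) and the titin gene Ttn (-1.43, adjusted p = 0.094), chosen after their values were seen, did not pass over all genes either.

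The cardiac list had a median of -0.69, with 1 member called over all genes and 18 adjusted over the list alone (adjusted p = 5.39e-25, and adjusted p = 0.079 with an estimated correlation). Another assignment of the 72 h arrays to exposed and control called 14 lists, as many as the real one. The number of lists called at 72 h therefore does not set exposure apart from wrong labels. The third exposed array lay farthest from the others: cardiac list means were 7.54, 7.61 and 7.65 in the controls and 7.20, 7.14 and 6.47 in the exposed arrays, and the median change was -0.42 without that array. Mesenchyme and matrix genes had a median of -0.25 (adjusted p = 6.67e-10, and adjusted p = 0.092 with an estimated correlation), with 9 of 20 down adjusted over the list alone and 0 over all genes. Without the third exposed array their median was -0.14. Acta2 in this list had a change of -1.28 (adjusted p = 0.131), which was -0.66 without the third array of both groups.

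Blood vessel genes were lower too. The blood and endothelium list had a median of -0.16 with 7 of 25 down adjusted over the list alone (adjusted p = 3.88e-05, and adjusted p = 0.11 with an estimated correlation), led by Cdh5 at -1.09 (adjusted p = 0.109). Angiogenesis signalling had a median of -0.17, with 9 of 23 down and 2 up adjusted over the list alone (adjusted p = 2.25e-06, and adjusted p = 0.079 with an estimated correlation), led by the vessel-stabilising ligand gene Angpt1 at -0.93 (adjusted p = 0.126), or -0.59 as the mean of its probe sets. BMP targets had a median of -0.23 with 6 of 11 down adjusted over the list alone (adjusted p = 0.000257, and adjusted p = 0.22 with an estimated correlation), among them the heart transcription factor gene Hand1 at -0.67 (adjusted p = 0.299). The third exposed array carried part of each: without it the blood, angiogenesis and BMP medians were -0.12, -0.12 and -0.17, and without the third array of both groups -0.11, -0.10 and -0.12.

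Neural genes were higher at 72 h. The neural ectoderm list had a median of 0.34 with 18 of 20 members above 0 and 9 up adjusted over the list alone (adjusted p = 1.29e-11, and adjusted p = 0.079 with an estimated correlation). Fabp7, a fatty acid binding protein of radial glia, had a change of 1.37 ± 0.27 (SE; adjusted p = 0.0961), or 0.72 without the third array of both groups, where its changes at 24 h and 48 h were -0.66 (adjusted p = 0.163) and -0.92 (adjusted p = 0.0532). Olig2, chosen after its value was seen, had one of 0.99 (adjusted p = 0.113). The controls also differed among themselves, with neural list means of 6.28, 6.39 and 5.94 against 6.54, 6.50 and 6.94 in the exposed arrays. The median was 0.21 without the third control array and 0.09 without the third array of both groups. The epiblast list had a median of 0.20 (2 of 12 up adjusted over the list alone; adjusted p = 0.000116, and adjusted p = 0.29 with an estimated correlation), which was 0.01 and no longer called without the third array of both groups.

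**Figure D3:**
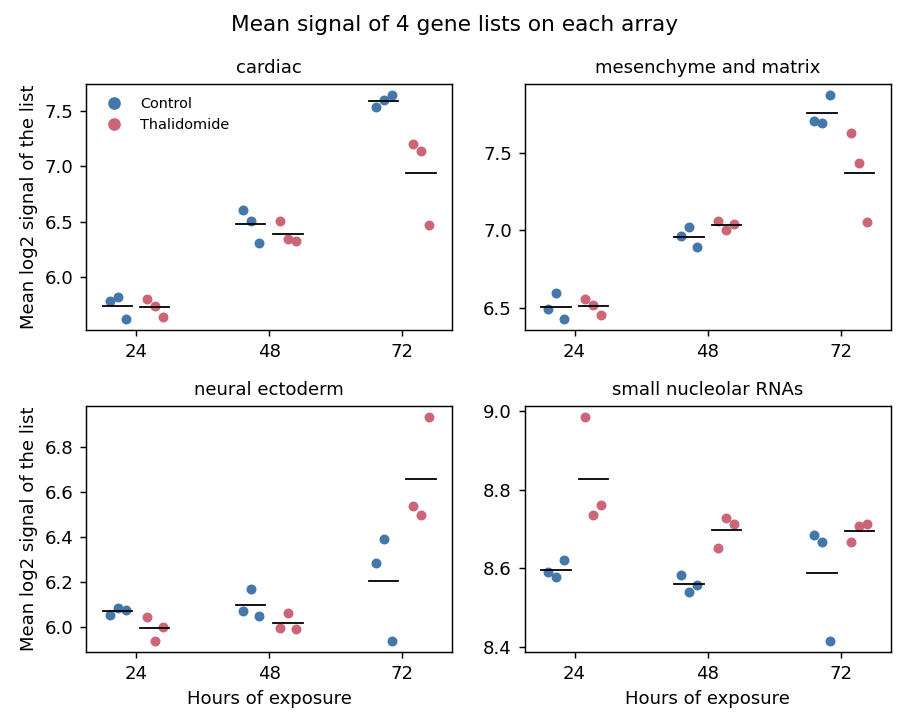
Mean log2 signal of the members of 4 gene lists on each array by hours of exposure. Points are arrays (3 per group), bars are group means and colours mark treatment. At 72 h all exposed arrays lie below all controls for the cardiac list and above them for the neural list.

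The remaining lists called at 72 h had medians within 0.13 of 0. They were p53 targets (0.09, adjusted p = 0.000271; 5 of 21 up adjusted over the list alone, with Plk3 at 0.58), pluripotency (0.10, adjusted p = 0.0338), cholesterol synthesis (-0.08, adjusted p = 0.000738), limb development (-0.05, adjusted p = 0.016), small nucleolar RNAs (0.11, adjusted p = 1.32e-05), replication histones (0.13, adjusted p = 0.00463) and ribosomal protein genes (0.03, adjusted p = 0.0196). With an estimated correlation these 7 had adjusted p-values from 0.29 to 0.53. Without the third control array of 72 h the medians of the small nucleolar RNAs and the histones were 0.02 and 0.08, and neither was called. The pluripotency list was not called without the first control (0.12) or the third exposed array (0.04) or among genes at or above the median signal (0.07), the limb list not without the second control (-0.05) or the third exposed array (-0.03), and the ribosomal list not in 4 of the 6 fits that left out 1 array. Of the other lists, the adjusted p was 0.0641 for FGF-ERK targets, 0.143 for the unfolded protein response, 0.226 for glycolysis and hypoxia, 0.346 for canonical Wnt targets, 0.375 for Hox genes and 0.414 for both definitive and extraembryonic endoderm. It was 0.464 for the primitive streak, 0.499 for the mitotic cell cycle and the two-cell-like state, 0.651 for germ cells, 0.683 for the cereblon ligase, 0.774 for trophoblast and aryl hydrocarbon receptor targets, and 0.887 for the NRF2 and the retinoic acid responses. Without the third array of both groups, glycolysis and hypoxia (-0.14, adjusted p = 9.94e-05), the unfolded protein response (-0.07, adjusted p = 0.00699), extraembryonic endoderm (0.09, adjusted p = 0.0242) and definitive endoderm (0.09, adjusted p = 0.047) were called. Of 11 alternative settings extraembryonic endoderm was called in 4, glycolysis, Hox genes and FGF-ERK targets in 3 each, the unfolded protein response in 2 and definitive endoderm in 1.

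**Figure D4:**
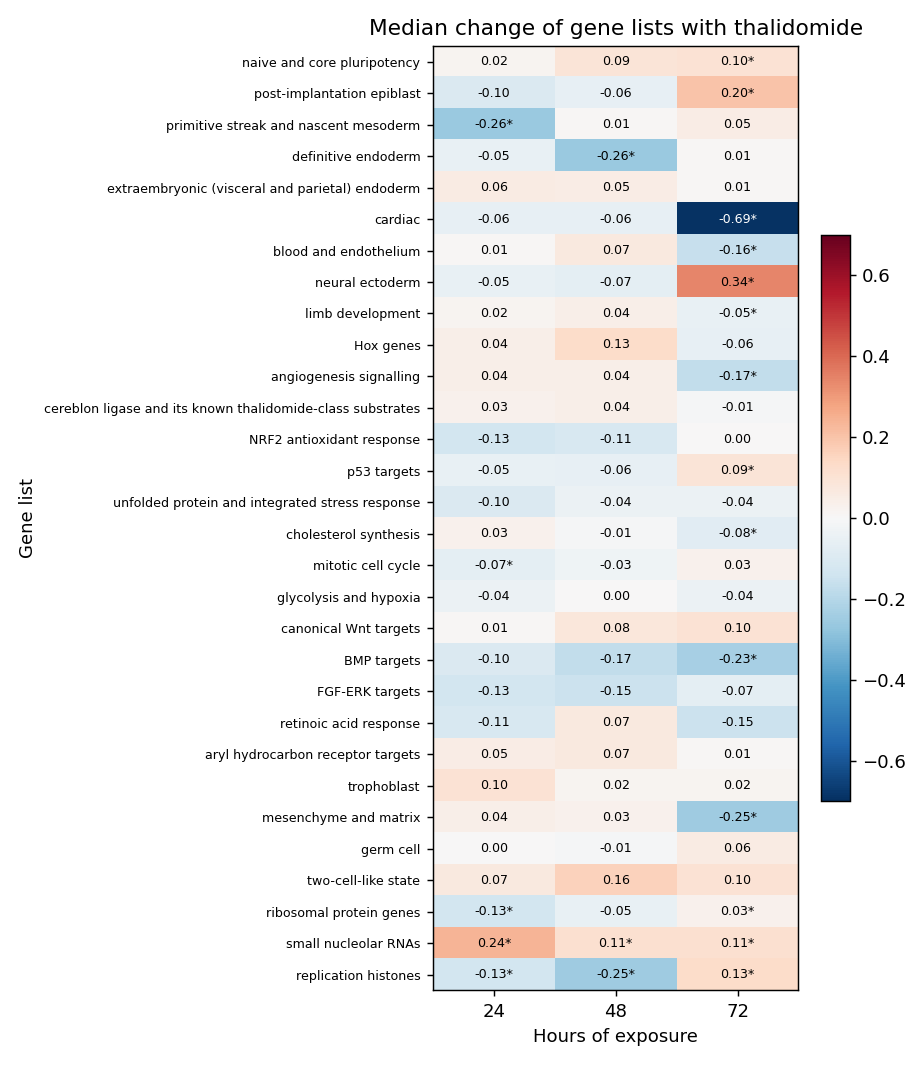
Median log2 change (exposed minus control) of the 30 gene lists at 24, 48 and 72 h, shown by colour and number, with a star where the list passed camera at the preset correlation. The cardiac list stands at -0.69 and the neural list at 0.34 at 72 h.

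The 2 genes called at 72 h stand against 2023 with an unadjusted p under 0.05, where 1109 would be by chance. The count was 0 without the first or the third control array, 1 without the second control, 81 without the first exposed array, 13 without the second and 0 without the third. It was 30 with an intensity trend and the robust option together (25 down, 5 up) and 38 at or above the median signal (28 down, 10 up), with 18 genes in both sets, and Myh6 passed in both (adjusted p = 0.0282 and 0.0195, over a range of 0.00789 to 0.432).

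Averaged over the 3 times, 2890 genes changed (871 up and 2019 down, 69.9% down), of which 16 by at least 1.5-fold. Cyclic loess gave 868 up and 1177 down (57.6% down), and the filter at the median signal 650 up and 2673 down (80.4% down). Crbn had a mean change of -0.26 (adjusted p = 0.0048) and Cul4a one of -0.26 (adjusted p = 0.00087), both named here after their values were seen. The cardiac list had a median of -0.26 with 7 of 25 down and 10 adjusted over the list alone (adjusted p = 0.00152), BMP targets -0.18 with 3 of 11 down and 4 adjusted over the list alone (adjusted p = 0.0137), and FGF-ERK targets -0.10 with 5 of 12 down in both counts (adjusted p = 0.0157). Small nucleolar RNAs had a median of 0.15 with 29 of 73 up and 38 adjusted over the list alone (adjusted p = 8.06e-12), and replication histones -0.14 with 4 of 25 down, and 9 down with 1 up adjusted over the list alone (adjusted p = 0.0137). For all 5 lists the call was lost at adjusted p = 0.77 with an estimated correlation. The FGF-ERK call was also lost after cyclic loess (median -0.05), and among genes at or above the median signal the cardiac (adjusted p = 0.141), BMP (adjusted p = 0.355), FGF-ERK (adjusted p = 0.355) and histone (adjusted p = 0.503) calls were lost. The histone call was lost without the second exposed replicate of 24 h too (adjusted p = 0.0639), and the cardiac median was -0.16 without the third exposed array of 72 h.

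The exposure effect itself was compared between times. The decreases of Sdhc and H2bc12 differed between 72 h and 48 h by 1.26 ± 0.12 and 1.35 ± 0.15 (SE; adjusted p = 0.000166 and 0.000716), since Sdhc had a change of -0.10 (adjusted p = 0.803) and H2bc12 one of 0.18 (adjusted p = 0.664) at 72 h. Bod1 (0.92) and Dexi (-0.85) differed likewise, in 13 and 15 of 20 alternative settings, and Sdhc and H2bc12 in all 20. Myh6 differed by -1.92 (adjusted p = 0.0301; 12 of 20 alternative settings), with an effect of 0.60 at 48 h (adjusted p = 0.101). In total 21 genes had a different effect at 72 h than at 48 h (14 higher, 7 lower) and 110 than at 24 h (85 higher, 25 lower). After cyclic loess these were 15 higher and 17 lower, and 38 higher and 28 lower. In differences from 24 h, time cannot be told apart from the re-analysis tag, which the exposed arrays of 48 h and 72 h lack. Between 72 h and 48 h an additive difference of the tag cancels. Between 48 h and 24 h limma called 0 genes, with 1701 at an unadjusted p under 0.05.

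Sall4 had changes of 0.06, -0.08 and 0.07 at 24, 48 and 72 h (adjusted p = 0.703, 0.528 and 0.85), and of -0.02, -0.11 and -0.13 as the mean of its probe sets, none of which passed. The arrays measure RNA, so protein levels of Sall4 and of the other genes in the cereblon ligase list were not seen. Crbn had a change of -0.11 ± 0.09 (SE; adjusted p = 0.824) at 72 h. The smaller change at 72 h was not shown to differ from that at 24 h (difference 0.27, adjusted p = 0.36).

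The exposure effects were also set against the control course, using control arrays that the effect does not share. Across the 3023 genes that changed from 24 h to 48 h in control, the effect at 72 h correlated with that change at r = -0.44 (rho = -0.42), and the value was -0.30, -0.28 and -0.48 with each exposed array on its own. Across all genes it was -0.26. The 24 h effect correlated with the control change from 48 h to 72 h at r = 0.31 (1448 genes), or 0.11 across all genes, and the 48 h effect with the control change from 24 h to 72 h at r = -0.11 (6095 genes). With each exposed array on its own these values were 0.34, 0.23 and 0.22 at 24 h and 0.05, -0.19 and -0.13 at 48 h. Genes are not independent replicates, so no p-value is given.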

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

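The tests of brightness and of the re-analysis tag for the first pattern, and those of the tag, of a general delay and of the share of cardiac cells for the second, were chosen only after the result was seen, as were the lists compared between 72 h and 48 h and the fits without the third array of both 72 h groups. A first version of the brightness test, which asked what share of the shared calls stays called after cyclic loess (52.2%, 296 of 567), lay close to its bound of 50% and was replaced after that value was seen. The test of the share of cardiac cells first compared the neural list with the extraembryonic endoderm and trophoblast lists (0.32, or 0.11 to 0.42 without 1 array and -0.04 without the third array of both groups), which decided nothing, and was replaced by the one below after these values were seen.

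These results were picked out because the effect of exposure differed between times by an interaction test. Between 72 h and 48 h, Sdhc differed by 1.26, H2bc12 by 1.35, Bod1 by 0.92, Dexi by -0.85, Myh6 by -1.92 and Tnfrsf10b by 0.78, and 21 genes passed in all. Of 20 alternative settings Sdhc and H2bc12 passed in 20, Dexi in 15, Bod1 in 13, Myh6 in 12 and Tnfrsf10b in 10. Between 72 h and 24 h, Sdhc differed by 1.17, H2bc12 by 1.25, Dexi by -1.01, Bod1 by 1.02, the carbonyl reductase gene Cbr1 by 0.68 and Stx6, a gene of vesicle transport, by -0.64, and 110 genes passed. Cbr1 and Stx6 passed in 19 of 20 alternative settings. The difference between 72 h and 24 h also spans the re-analysis tag, which the exposed arrays of 72 h lack, so its count may hold a part of the tag. List medians differed between 72 h and 48 h for cardiac genes (-0.54), mesenchyme and matrix (-0.30), angiogenesis signalling (-0.25), blood and endothelium (-0.22), Hox genes (-0.17) and limb development (-0.09), which were lower at 72 h. Those of histones (0.34), neural ectoderm (0.29), epiblast (0.27), definitive endoderm (0.27), p53 targets (0.14) and ribosomal protein genes (0.08) were higher. These calls were made by camera at the preset correlation, and the lowest adjusted p was 0.21 with an estimated correlation.

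The first pattern is the set of 501 genes, among them Sdhc, Bod1 and Mrpl34, that fell together at 24 h and 48 h, with a median of -0.04 at 72 h, where 66.3% kept their sign and few differed by test (Sdhc and Bod1 did, and Mrpl34 did not). For a shift of signal with brightness, the median change of the 501 shared decreases after cyclic loess was -0.32 at the time nearer to 0. It was -0.40 and -0.38 before, and only 239 of them stayed called at both times. These genes were picked in the same data for their decreases. Over all genes the brightest bin had medians of only -0.075 at 24 h and -0.058 at 48 h. Removing a shift of that size could hardly bring the median of the 501 near 0. The test therefore decides little, and brightness stays open as a part of the cause. A difference tied to the re-analysis tag is argued against, since the 24 h effect has the tag on both sides and still correlated with the 48 h effect more strongly than the 72 h effect did, by 0.35 in r (0.27 to 0.39 over fits without 1 array). RNA quality or labelling that also moves small nucleolar RNAs stays open: within groups the 2 sets of genes went in opposite directions at r = -0.38 (permutation p = 0.14 over 18 arrays), between the values that would decide. A response to thalidomide may also account for it, and the design has no second dose or compound to test this.

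The second pattern is the lower cardiac and higher neural lists at 72 h, for which neither a shift of cells from cardiac to neural fates nor a lower share of cardiac, mesenchyme and blood cells together was tested. One exposed replicate is argued against as the whole cause, since the cardiac median was -0.42 without the third exposed array and the other exposed arrays (7.20 and 7.14) lay below all controls. An additive difference of the tag is argued against for the cardiac list, since its median was -0.54 in the difference of effects between 72 h and 48 h, in which it cancels (-0.69 to -0.26 without 1 array, and -0.23 without the third array of both 72 h groups). A difference of the tag that is not the same at 48 h and 72 h does not cancel there and stays open. The neural list was not part of the test of the additive difference, whose bound was set after the result was seen. The cardiac value of -0.23 lay close to that bound. A general delay stays open: the neural median was 0.34 (0.21 to 0.45 without 1 array), where the control course moved that list by 0.12, but 0.09 without the third array of both groups, and the 72 h effect ran against the control course at r = -0.44. In control the primitive streak list fell from 6.66 ± 0.1 at 48 h to 6.11 ± 0.1 at 72 h (mean ± SD, n = 3). With exposure it was 6.17 ± 0.03 at 72 h, which goes against a general delay. The epiblast list (7.6 ± 0.04, 7.15 ± 0.13 and 7.35 ± 0.19 in the same order) lay toward a delay. Both lists were picked after their values were seen. A lower share of cardiac cells alone, raising all other cell types alike, stays open. Mesenchyme (-0.25) and blood and endothelium (-0.16) were lower, which goes against it. The neural list exceeded the higher of them by 0.50 (0.32 to 0.61 without 1 array, and 0.19 without the third array of both groups). This comparison was chosen after the results at 72 h had been seen, however, and the first version of the test decided nothing.

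Other splits of the same arrays were counted for each result. For 6 arrays there are 10 splits, too few for a share under 0.05: the real split called 1521 genes at 24 h, 1349 at 48 h and 2 at 72 h, and the highest other split 0 each time. For control time the real splits called 3023, 1448 and 6095 genes and the highest other 0. In each of these 6 results 1 split, the real one, gave as many. For lists the real split called 5 at 24 h (highest other 4, and 1 split as many), 3 at 48 h (other 5, and 5 splits as many), 14 at 72 h (other 14, and 3 splits as many) and 19 for control time (other 17, and 1 split as many). The numbers of lists called at 48 h and 72 h were thus no higher than the highest from other splits.

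For the mean over times, 1 of 100 splits gave as many as the real 2890 genes, and the highest other gave 1, so chance was excluded. For its lists 59 of 100 splits gave as many as the real 5 (highest other 13), so chance was not excluded. Between 48 h and 24 h limma called 0 genes (1701 at an unadjusted p under 0.05; highest other 1), so 100 of 100 splits gave as many by construction, which decides nothing. At least 21 genes between 72 h and 48 h were called in 9 of 100 splits (highest other 388), and at least 110 between 72 h and 24 h in 9 of 100 (highest other 599), so these counts do not exclude chance. All 8 other splits in each set, however, kept or swapped every exposed label at 1 of the 2 times and so carry the exposure effect of that time, which makes them no measure of what a lack of difference would give. The split with 388 calls kept 3 of 3 exposed labels at 48 h and 1 of 3 at 72 h, and the one with 599 kept 0 of 3 at 24 h and 2 of 3 at 72 h. Such high counts point to a structure of the samples, the shared exposure effect within single times.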

How the results depend on the processing

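The alternatives were chosen before the data were examined, except leaving out the third replicate of both 72 h groups and comparing lists between 72 h and 48 h, which were chosen after seeing the data. Among the named genes and the lists no called value changed sign in these settings, and neither did a correlation with the control course. Values that did not pass, such as those of Sall4, did in some settings. The signs of genes not named were not followed from setting to setting. With the first exposed array on its own the correlation at 48 h was 0.05, against -0.11 with all arrays. The balance of up and down turned for 72 h against 48 h after cyclic loess (14 and 7 to 15 and 17) and for control 72 h against 24 h (2914 and 3181) after cyclic loess (3246 and 2836) and with all probe sets (3986 and 3714). For control 48 h against 24 h (1536 and 1487) it turned with array weights (1797 and 1805). Below, counts of genes are for exposure at 24 h, 48 h and 72 h, the mean over times, and the differences 72 h against 48 h and 72 h against 24 h. Dim probe sets could not be set against background, and 3 arrays per group limit every count. Where no cause is named, the cause was not tested.

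An added limit of 1.5-fold left 122, 123, 2 and 16 genes, 71 for 72 h against 24 h, 749, 461 and 1664 for control time (48 h against 24 h, 72 h against 48 h, 72 h against 24 h) and 34 shared between 24 h and 48 h. With only the groups of a contrast in the fit, and so fewer arrays, the counts were 121 at 24 h, 163 at 48 h, 0 at 72 h, 2 and 5. The intensity trend with the robust option gave 30 at 72 h, 350 and 532, with overlaps of 941 (24 h and 48 h), 2 (24 h and 72 h) and 1 (48 h and 72 h). Genes at or above the median signal gave 38 at 72 h, 365 and 640, overlaps of 1052, 4 and 3, and 2 lists at 24 h and 3 for the mean. All probe sets gave 0 at 72 h and 52 for 72 h against 24 h. Cyclic loess gave 32 and 66 for the differences, and array weights 89 for 72 h against 48 h. Limma's counts of 0 at 72 h stand against 2023 genes at an unadjusted p under 0.05 in the fit of all arrays. With an estimated correlation 0 lists were called at 24 h, 0 at 48 h, 0 at 72 h, 0 for the mean and 1 for control time. Without the third replicate of both 72 h groups 0 genes were called at 72 h and 1909 for the mean, and 8 lists for the mean. Across all genes, the correlation with the control course was 0.11 at 24 h and -0.26 at 72 h.

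With the replicate number as a block the counts were 658, 595, 0 and 1869, 5 and 70 for the differences, and 214 shared between 24 h and 48 h. The labels do not say that the numbers pair samples. Exposed and control arrays of the same number correlated at r from -0.14 to 0.12, and 2 of 9 correlated best with their own number.

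Leaving out 1 array gave 581 to 1295 genes at 24 h, 494 to 1280 at 48 h, 0 to 81 at 72 h, 2068 to 3110 for the mean, 2 to 31 and 8 to 119 for the differences of 72 h, 0 between 48 h and 24 h, and 2026 to 2643, 805 to 1091 and 4938 to 5512 for control time. Lists ran from 3 to 6, 3 to 4, 12 to 16, 4 to 7 and 18 to 22, and the correlations with the control course from 0.24 to 0.34, -0.22 to -0.02 and -0.45 to -0.33. Counts moved by over 1.5 times at 24 h without control 1 (665), control 3 (581, and 3 lists) or exposed 1 (655). At 48 h they did without control 1 (598), 2 (708) or 3 (612) or exposed 2 (494) or 3 (584). At 72 h they did without control 1 (0), 2 (1) or 3 (0) or exposed 1 (81), 2 (13) or 3 (0), and for control 72 h against 48 h without the third control of 48 h (805) or of 72 h (824). The difference 72 h against 48 h had 13, 2 and 7 genes without controls 1 to 3 of 48 h, 10, 2 and 2 without those of 72 h, 9 and 2 without exposed 1 and 3 of 48 h, and 4 and 10 without exposed 1 and 3 of 72 h. The difference 72 h against 24 h had 27, 50 and 18 without controls 1 to 3 of 24 h, 54 and 8 without controls 1 and 3 of 72 h, 25 and 60 without exposed 1 and 2 of 24 h, and 25 and 42 without exposed 1 and 3 of 72 h.

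Of the values of named genes, 247 lost and 8 gained their call in the fits without 1 array and 1425 kept their side. Losses were 73 with only the groups of the contrast, 41 with the block, 28 with cyclic loess and 26 with all probe sets. Of list values 45 lost their call with an estimated correlation, and 20 lost and 28 gained it without 1 array.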

Other observations

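The class of mitochondrial genes below was chosen after the decreases of Sdhc and Mrpl34 had been seen, and the genes given below are named after their values were seen.

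Many nuclear genes for the mitochondrial ribosome and the respiratory chain fell with exposure at 24 h and 48 h. Mrps21 and Mrpl52, proteins of the ribosome that makes the mitochondrially encoded subunits, had changes of -0.76 (adjusted p = 0.00017) and -0.65 (adjusted p = 0.00017) at 24 h and of -0.82 (adjusted p = 0.00015) and -0.53 (adjusted p = 0.0011) at 48 h. Ndufb8 and Ndufb9, subunits of complex I, had changes of -0.74 (adjusted p = 0.00056) and -0.40 (adjusted p = 0.0022) at 24 h. Sdhaf1, an assembly factor of the complex that holds Sdhc, had one of -0.59 (adjusted p = 0.0012) at 24 h, but is not a member of the class tested below. At 72 h Mrps21 had a change of -0.09 (adjusted p = 0.83) and Mrpl52 one of 0.00.

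The hypothesis that this class fell beyond genes of like signal and genomic span was tested on its 151 genes against 10000 matched random lists. The class median was -0.19 at 24 h and -0.15 at 48 h, where the random lists had -0.09 and -0.07, and at most 1 of the random lists was as low at either time. Such lists hold unrelated genes, so they measure the drawing of genes. They do not allow for correlation among the genes of the class or for the spread between replicates. None of the gene lists stayed called at 24 h or 48 h with an estimated correlation, which was not estimated for this class. Over all genes, 47 members fell at 24 h, and 27 fell and 1 rose at 48 h. After cyclic loess the medians were -0.13 and -0.10 against -0.03 and -0.02, with 0 random lists as low. At 72 h the median was 0.00 and 8285 random lists were as low. Signs of RNA quality moved at the same times. The median of ribosomal protein genes was -0.13 at 24 h, and that of replication histones -0.13 at 24 h and -0.25 at 48 h. Small nucleolar RNAs had medians of 0.24 at 24 h and 0.11 at 48 h. RNA quality or labelling therefore stays open for this class as it does for Sdhc and Mrpl34 above. The result holds for this set of data, on which the class was also found, and needs an independent one.

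The hypothesis that exposure at 72 h moves genes against their control course was tested with the correlation of -0.44 given above. It lay below the range of the other assignments of the 6 arrays (-0.42 to 0.42), and 1 of 10 splits, the real one, gave a value as large in size, too few for a share under 0.05. At 24 h 3 of 10 splits and at 48 h 8 of 10 were as large.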
